A study of Rattus norvegicus with 8 samples.

How the data were processed

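Total RNA from synovial tissue of rat knees was measured on 8 Agilent rat miRNA arrays with 1 colour (Cy3), 4 after ACLT and 4 after sham surgery. Per the labels, the RNA was isolated with RNAiso plus, and Cy3-labelled cRNA was prepared from 50 ng of total RNA with a Low Input Quick Amp kit; that kit is made for messenger RNA, and whether it was used for these arrays is not settled by the sources used here. Groups and replicate numbers come from the sample titles. All arrays lay on 1 slide and had 1 scan date, so slide and scan are not batches. Slide row 1 held replicates 1 and 2 of both groups and row 2 held replicates 3 and 4, and row was tried as a block and by fitting each row alone.

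Per the file headers, the authors' scanner images were read with Agilent Feature Extraction 10.7.3.1, protocol miRNA_107_Sep09, array design 070154. The values used are the processed signals, an intensity in linear units that Feature Extraction had background-subtracted, per the file headers, and had not scaled between arrays. The authors' deposited value table equals Feature Extraction's summary per miRNA exactly on every array (largest difference 0), so its scale is linear intensity with no centring and no scaling; each column's median was 0.1, the value given where a miRNA was not detected. Its name for a row was matched to the scanner files through the miRNA name. The grid names build rn4. The gene table used here belongs to GRCr8, so no coordinates are printed; it was used for names only, and 108 of 113 tested miRNAs matched a precursor gene in it.

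Spots marked as outliers (9.01% to 11.1% of the spots per array) and control spots were left out, and the spots of a probe were averaged. A probe counted as well above background on an array where at least 0.5 of its spots did. Each array was divided by its 75th percentile over the 136 probes well above background on all arrays, since few of the 1806 probes were detected. Values under a floor of 0.0449 were then set to it, and log2 was taken, so the floor lies at -4.48. A miRNA, which has 1 to 4 probes, was represented by its brightest probe by the mean over all 8 arrays, a choice that does not use the groups. Where a miRNA had several probes, the differences of miR-21-5p lay between 0.67 and 0.77, those of miR-34a-5p between 0.41 and 0.58 and those of miR-125b-5p between -0.52 and -0.38; for miR-199a-5p the probes disagreed in sign (-0.04 and 0.09). Tested were the 113 miRNAs that Feature Extraction called detected on all 4 arrays of at least 1 group; 78 of them were above the floor on every array. Where no probe of a miRNA was well above background on any array of 1 group, the fold is only an approximate bound. It sets the brighter group's mean against a mean over the dim group's arrays and leaves sampling error out. The latter mean takes, per array, the higher of the lowest signal well above background and the probe's own.

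ACLT was compared with sham by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, all 8 arrays, no covariate), with Benjamini-Hochberg adjustment at 0.05; limma noted zero variance for the 2 miRNAs at the floor everywhere. The 21 lists were tested with camera at its preset correlation of 0.01 where at least 3 members were tested, which held for 17, with adjustment over the lists; camera with an estimated correlation and directional fry were alternatives. Measures with 1 value per array were compared by exact two-sided permutation over 70 arrangements. Intervals are at 95%. Tests, lists, the rule for named miRNAs and most alternatives were set before the data were examined. The rule named the 20 miRNAs with the smallest unadjusted p where under 10 passed, 15 fixed miRNAs where tested, and up to 4 members of each list with the smallest p; of these list members the text names 2 per list and those with an array far from the others of its group, and it names miRNAs outside the rule only where it says that they were chosen after their values were seen. Of the fixed miRNAs, miR-155-5p and miR-133a-3p were not tested, being detected on 2 and 5 arrays. miR-378a-3p and miR-486-5p are on no array under those names.

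Alternatives were other scalings, another summary of probes, the authors' value table, other filters and floors, other variance models, slide row, replicate number as a block, and leaving out each array. Background correction by normexp on mean signals was planned and could not be run, as the mean signal is not among the columns used here; it was run on median signals with an offset of 50 as an added alternative. The depth of an array shows as its signal over background: 10.5% to 17.0% of spots were well above background. The steps were tested on simulated data: in 100 runs with the spread of these arrays, 20 of 113 miRNAs were given known differences between ACLT and sham arrays, and 90.8% of 4-fold, 72.8% of 2-fold and 48.6% of 1.5-fold differences were recovered, with 5.32% of calls false. A shift of 0.5 in 1 list, the let-7 family with 9 tested members, was found in 100% of runs. Other lists, most of them with fewer tested members, were not tried. The simulated miRNAs varied independently, which these arrays' miRNAs do not. No floor was applied to the simulated values, though their spread came from floored ones. The changed miRNAs were drawn from all 113, among them the 33 at the floor on some arrays and the 2 at it on all. The floor narrowed the spread of these, so the pooled shares do not hold for them and may be too high for the others. Recovery was not computed apart for miRNAs above the floor on every array.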

Results

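MicroRNA in synovial tissue, the lining of the joint, was measured on 8 single-colour arrays, each with RNA from a left knee of Sprague-Dawley rats. In 4 samples the anterior cruciate ligament, which stabilizes the knee, had been cut (ACLT, a surgical model of osteoarthritis), and in 4 the ligament had been exposed and left intact (sham). The comparison asks which miRNAs of the synovium differ after the ligament is cut. The labels disagree on the time of sampling: the title names 14 days and the protocol 2 weeks, while the design text names 7 days. The labels number the replicates and do not say that they were separate animals, so p-values measure only the spread between these samples, which may be technical. Of 758 rat miRNAs on the array, 199 were detected on at least 1 array and 103 on all 8. The number detected per array was 140.25 ± 23.2 (SD, n = 4) after ACLT and 134.75 ± 33.4 (SD, n = 4) after sham surgery. An exact two-sided permutation test did not separate the groups (p = 0.83, adjusted p = 0.943 over 5 measures of the arrays, the smallest possible p being 0.0286). More miRNAs were detected on sham replicate 4 (184), ACLT replicate 2 (169) and ACLT replicate 1 (149) than on the other arrays (111 to 126).

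No miRNA separated the synovium after ACLT from the sham synovium past the test over all miRNAs. The smallest p-values belonged to lower means after ACLT of miR-125b-5p, a relative of the worm miRNA lin-4, and miR-223-3p, a miRNA of myeloid cells. miR-125b-5p had a log2 signal of 1.38 ± 0.06 (SD, n = 4) after ACLT and 1.76 ± 0.26 (SD, n = 4) after sham surgery, relative to each array's 75th percentile, which is 1.30-fold. miR-223-3p was at -3.94 ± 0.12 and -3.63 ± 0.19 (SD, n = 4 each). The mean of miR-21-5p, which is induced in inflammation and fibrosis, was 1.59-fold higher after ACLT, at 1.88 ± 0.46 against 1.21 ± 0.51 (SD, n = 4 each), and that of miR-34a-5p, a transcriptional target of p53, 1.49-fold higher, at -1.07 ± 0.30 against -1.65 ± 0.49 (SD, n = 4 each). The 95% interval of the log2 difference included 0 for miR-21-5p (0.67, -0.09 to 1.43) and miR-34a-5p (0.58, -0.06 to 1.22). Without sham replicate 3 the difference of miR-34a-5p was 0.38.

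By limma with Benjamini-Hochberg adjustment 0 of 113 tested miRNAs passed an adjusted p of 0.05, and 8 had an unadjusted p under 0.05, where 5.65 are expected by chance. The smallest adjusted p was 0.644. All 8 had a lower mean after ACLT. That balance turned with the 75th percentile without striated muscle probes (6 of 8 higher), without ACLT replicate 2 (5 of 8 higher) and within slide row 2 (6 of 10 higher). Besides miR-125b-5p (log2 difference -0.38, SE 0.13) and miR-223-3p (-0.32, SE 0.11) they were miR-6216 (-1.19, SE 0.46), miR-324-3p (-0.52, SE 0.21), miR-1896, miR-320-3p, miR-465-5p and miR-466d. All 4 ACLT arrays lay below the sham mean for each of these 8 miRNAs, and above it for miR-21-5p and miR-34a-5p. The 8 were picked by their p-values in these same arrays, so lying on 1 side is no separate check of them. It also held for miRNAs with differences close to 0, such as miR-365-3p (-0.0054) and miR-539-5p (-0.037). miR-1896, miR-320-3p, miR-465-5p and miR-466d were at the floor on all 4 ACLT arrays and on sham replicate 4. The size of their differences depends on the floor and rests on the other sham arrays. Sham replicate 4, the brightest array, was also the lowest sham array for miR-6216, miR-324-3p and miR-125b-5p, and the highest for miR-223-3p. miR-465-5p was not well above background on any ACLT array and was so on 2 sham arrays, which gives a bound of at least 1.18-fold higher after sham surgery (limma adjusted p = 0.644). miR-466d was well above background on 1 sham array and on no ACLT array, with an approximate bound of 1.15-fold higher after sham surgery (limma adjusted p = 0.644). Its interval was -0.42 to -0.0077. Sham replicate 4 was at the floor for both miRNAs, so neither bound is strict. The scanner software called miR-466d detected on 4 of 4 sham arrays and 0 of 4 ACLT arrays, and Fisher's exact test gave p = 0.0286 (adjusted p = 1 over 96 miRNAs detected on some arrays only). The values of the groups stayed apart without overlap for 0 of 113 tested miRNAs, where chance gives 2.86%, or 3.23 miRNAs.

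**Figure D1:**
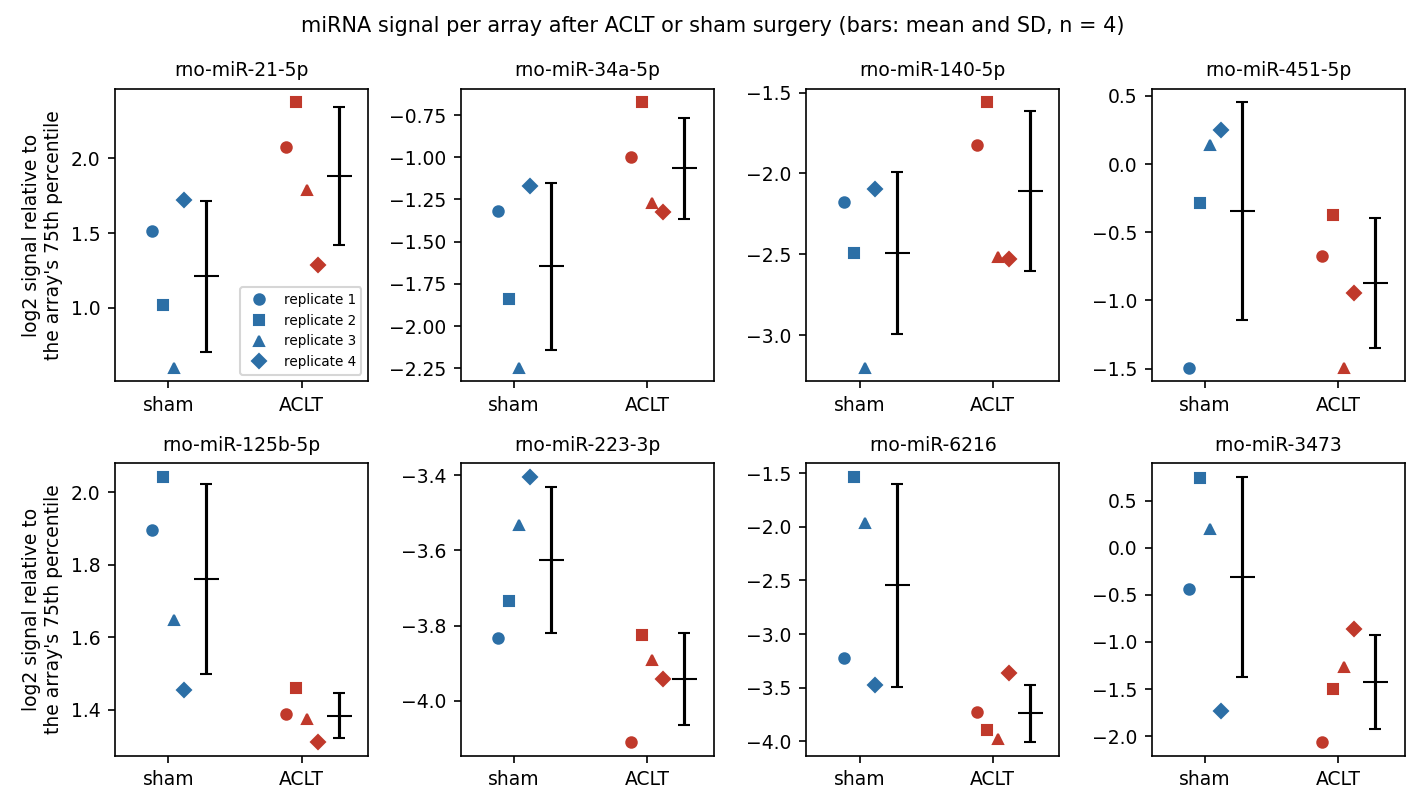
log2 signal of 8 miRNAs on each array, relative to the array's 75th percentile, after sham surgery (blue) and ACLT (red), with a marker for each replicate and a black bar for the mean and SD (n = 4). miR-125b-5p lies at 1.38 ± 0.06 after ACLT and 1.76 ± 0.26 after sham surgery, and the groups overlap in every panel.

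Across the tested miRNAs the difference was positive for 38, negative for 73 and 0 for 2 that were at the floor on all arrays, with a median of -0.07. That balance moved with the scaling, the median being 0.24 with the 75th percentile taken over all probes, 0.19 with no scaling, 0.21 in the authors' value table and -0.26 with scaling to the labelling spike-in probes. The differences of miR-21-5p and miR-34a-5p were positive and those of miR-125b-5p, miR-6216 and miR-3473 negative under all 30 alternatives run for each, though that of miR-125b-5p came to -5.4e-05 with the 75th percentile over all probes. miR-223-3p turned positive under 2 of its 30, reaching 0.061 with that percentile. The 30 are not separate checks of a sign. The filters, eBayes with trend and the slide row and replicate blocks leave an estimate unchanged, and the fits without 1 array share most of their arrays. miR-3473 was at -1.43 ± 0.50 after ACLT and -0.31 ± 1.06 after sham surgery (SD, n = 4 each), and miR-494-3p, of the imprinted Dlk1-Dio3 region, at -3.02 ± 1.10 and -1.86 ± 1.55 (SD, n = 4 each). For miR-494-3p, sham replicate 4 lay at -4.14 and the other sham arrays at -1.56 to -0.78. Its difference was -2.69 within slide row 1 and 0.37 within row 2. For miR-3473, sham replicate 4 lay at -1.73 and the other sham arrays at -0.44 to 0.74. The difference of miR-3473 was -1.93 within slide row 1 and -0.30 within row 2. The arrays lay in 2 rows of the slide, with replicates 1 and 2 of both groups in row 1. Within row 1 miR-21-5p differed by 0.96 and miR-125b-5p by -0.55, and within row 2 by 0.38 and -0.21. In row 1, where both ACLT arrays were brighter than both sham arrays, 8 miRNAs fell relative to the array's 75th percentile (limma, adjusted p under 0.05), of which 4 had a positive difference with unscaled signals (-1.06 to 0.88), and within row 2 limma called 0 (10 at an unadjusted p under 0.05). Some of the 8 called in row 1 were at the floor on both ACLT arrays there. The floor sets the size of their scaled differences and narrows their spread.

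Of 21 preset miRNA lists, the fibroblast and fibrosis-associated list and the miR-23/27/24 clusters rose relative to the other miRNAs by camera with its preset correlation, and neither did with an estimated correlation. In the fibroblast and fibrosis-associated list, 4 of 5 tested members had a positive difference (median 0.09, mean 0.29, camera adjusted p = 0.0293, adjusted p = 0.769 with an estimated correlation), with a median of -0.08 under labelling spike-in scaling. Its highest differences were those of miR-21-5p and miR-34a-5p, while miR-214-3p (0.09) and miR-199a-5p (0.09), which are abundant in mesenchymal cells, lay close to 0 and turned negative under that scaling. In the miR-23/27/24 clusters all 5 members had a positive difference (median 0.09, camera adjusted p = 0.0293, adjusted p = 0.769 with an estimated correlation), among them miR-27a-3p (0.12) and miR-27b-3p (0.14), and the median was negative under 2 of 6 other scalings, down to -0.14 with quantile normalization. Within slide row 1 the fibroblast list had a median of 0.22 (camera adjusted p = 0.0515) and within row 2 of 0.17 (adjusted p = 0.706). The miR-23/27/24 clusters had 0.0072 (camera adjusted p = 0.524) and 0.17 (adjusted p = 0.0712). Camera called 0 lists with the 75th percentile over all probes, quantile normalization, no scaling, the Feature Extraction summary and the authors' value table. Both calls were also lost without some single arrays. The fibroblast list lost its call without ACLT replicate 2 (camera adjusted p = 0.268) or sham replicate 3 (0.102), where its median came to 0.012 and -0.014. It also lost the call without ACLT replicate 1 (camera adjusted p = 0.128), sham replicate 2 (0.0562) or sham replicate 4 (0.112), where the median was 0.11, 0.17 and 0.10. The miR-23/27/24 clusters lost theirs without sham replicate 3 (camera adjusted p = 0.153), where the median came to 0.0075. They also lost it without ACLT replicate 1 (camera adjusted p = 0.128), ACLT replicate 2 (0.114), ACLT replicate 3 (0.113) or sham replicate 4 (0.112), with medians of 0.09 to 0.12. Directional fry, which asks whether a list moves one way on balance, passed 0 lists (smallest adjusted p = 0.767), and 0 members of any list passed by limma over all miRNAs or adjusted over the list alone.

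Of the markers of other cells that synovial tissue can hold, no list with at least 3 tested members passed camera. The 4 tested leukocyte miRNAs all had negative differences (median -0.18, camera adjusted p = 0.344), among them miR-146a-5p (-0.13) and miR-142-3p (-0.15), and the median turned positive under 5 of 6 other scalings. Of 3 erythroid miRNAs 2 were negative, miR-451-5p (-0.53, SE 0.43) and miR-144-3p (-0.69, SE 0.38), and the median of -0.53 kept its sign under all 6 (camera adjusted p = 0.620). It ran from -0.91 without sham replicate 1 to -0.32 without ACLT replicate 3 and -0.33 without sham replicate 4. The third erythroid member differed by 0.14 and was at the floor on 4 arrays. Within slide row 1 miR-451-5p had a positive difference, and the erythroid median was far smaller in size. Cartilage miRNAs had a median of 0.25, positive under all 6 (camera adjusted p = 0.345), with miR-140-5p at -2.11 ± 0.49 after ACLT and -2.49 ± 0.50 after sham surgery (SD, n = 4 each) and miR-140-3p at a difference of 0.25. The cartilage median came to 0.034 without sham replicate 3 and 0.074 without ACLT replicate 2, and it was 0.46 without sham replicate 1 and 0.38 without ACLT replicate 3. The single tested smooth muscle miRNA, miR-143-3p, differed by -0.30 (SE 0.14) and the single endothelial one, miR-126a-3p, by -0.20 (SE 0.14), both positive with the 75th percentile over all probes, with no scaling and in the authors' value table. On sham replicate 2 miR-143-3p lay at 0.70, against 0.07 to 0.45 on the other sham arrays. The single tested neural miRNA differed by 0.12, and 0 of 10 epithelial miRNAs were detected on any array. The 5 tested adipose miRNAs had a median of -0.0054, positive under 5 of 6 other scalings (camera adjusted p = 0.744), with miR-103-3p at -0.15 and miR-107-3p at 0.10.

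Among families and clusters none but the miR-23/27/24 clusters passed. The 4 tested members of the miR-99, miR-100 and miR-125 group all had negative differences, with a median of -0.23 (camera adjusted p = 0.152) that turned positive under 3 of 6 other scalings, up to 0.14. miR-100-5p was at -0.23. The 3 tested members of the miR-181 family were negative, with a median of -0.32 (camera adjusted p = 0.344) that turned positive under 2 of the 6. The miR-29 family, which targets collagen messages, had 3 of 3 positive differences, with miR-29c-3p at 0.31 (SE 0.20) and miR-29b-3p at 0.07, and a median of 0.07 (camera adjusted p = 0.152) that was -0.11 with labelling spike-in scaling and -0.031 without sham replicate 3. Members of the miR-17-92 and paralogous clusters were negative in 5 of 5 (median -0.13, camera adjusted p = 0.439, sign turned under 5 of the 6) and of the miR-15/16 family in 5 of 6 (median -0.18, camera adjusted p = 0.620, turned under 4). The Dlk1-Dio3 imprinted cluster had 5 negative differences and 1 of 0 (median -0.08, camera adjusted p = 0.744, turned under 5). The inflammation-responsive list (median -0.05, mean 0.07, camera adjusted p = 0.744), the osteoarthritis-associated list (median -0.07, mean 0.05, camera adjusted p = 0.620) and the let-7 family (median -0.01, mean 0.02, camera adjusted p = 0.274) had medians and means of opposite sign, and the medians turned positive under 5, 5 and 4 of the 6 scalings. Camera placed these 3, the adipose list and the miR-30 family (median -0.08, turned under 5, camera adjusted p = 0.620) on the higher side, against the sign of their medians.

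**Figure D2:**
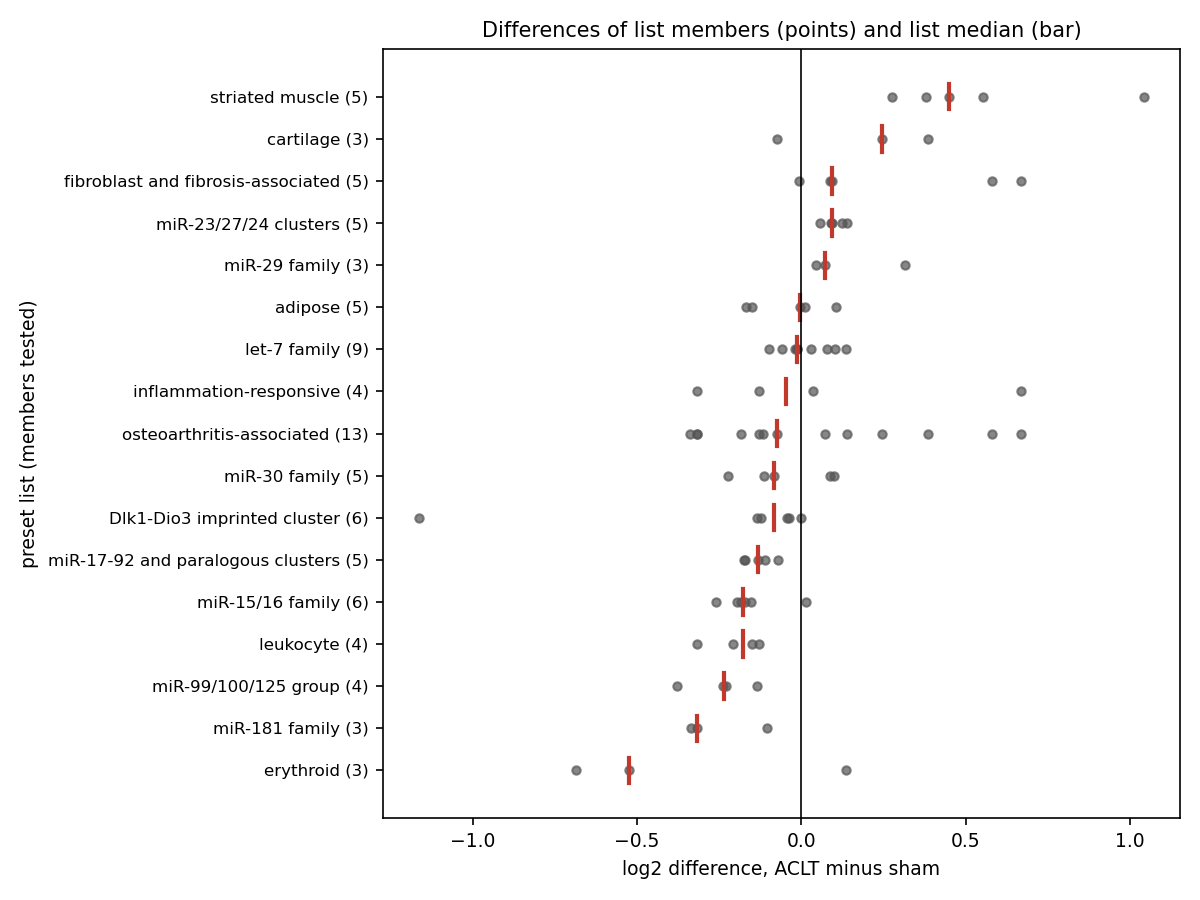
log2 difference, ACLT minus sham, of each tested member (points) and the median (red bar) of the 17 lists with at least 3 tested members, whose number stands in brackets. The medians run from -0.53 for erythroid to 0.45 for striated muscle, both of which kept their sign under 6 other scalings, while the medians of all lists but these and cartilage turned under at least 1.

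Striated muscle miRNAs differed far more between arrays than between groups. miR-1-3p, shared by skeletal and heart muscle, ranged over 92.4-fold and miR-206-3p, of skeletal muscle, over 105-fold, and the 5 tested members over 10.9-fold to 146-fold, between ACLT replicate 2 with the lowest and ACLT replicate 4 with the highest level. On ACLT replicate 2, miR-1-3p, miR-206-3p and miR-133a-5p were at the floor, so their ranges are lower bounds. The mean log2 level of the 5 members was -0.23 ± 2.83 after ACLT and -0.77 ± 0.83 after sham surgery (SD, n = 4 each), and an exact two-sided permutation test gave p = 0.83 (adjusted p = 0.943 over 5 measures). All 5 had a positive difference (median 0.45, camera adjusted p = 0.152, adjusted p = 0.783 with an estimated correlation). Without ACLT replicate 2 the median was 2.02 (camera adjusted p = 2.77e-08, adjusted p = 0.414 with an estimated correlation), and the exact two-sided permutation p of the mean level was 0.0857. Without sham replicate 3 it was 0.80 (camera adjusted p = 0.0322, adjusted p = 0.893 with an estimated correlation), and without ACLT replicate 3 or 4 it was negative, at -0.16 and -0.22. Within slide row 1 the median was -0.79 (camera adjusted p = 0.676) and within row 2 it was 1.77 (camera adjusted p = 0.000431, adjusted p = 0.814 with an estimated correlation). Of the members not tested, miR-133a-3p was detected on 5 arrays, 1 other on 4 and 3 on none.

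The arrays also differed in brightness within the groups. The 75th percentile of the probes well above background on all arrays was 797, 1097, 353 and 305 on ACLT replicates 1 to 4 and 289, 317, 353 and 1185 on the sham replicates. It did not separate the groups (exact two-sided permutation p = 0.857, adjusted p = 0.943 over 5 measures). On all arrays 0 spots were saturated, and the number of arrays limits the precision of every value.

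**Figure D3:**
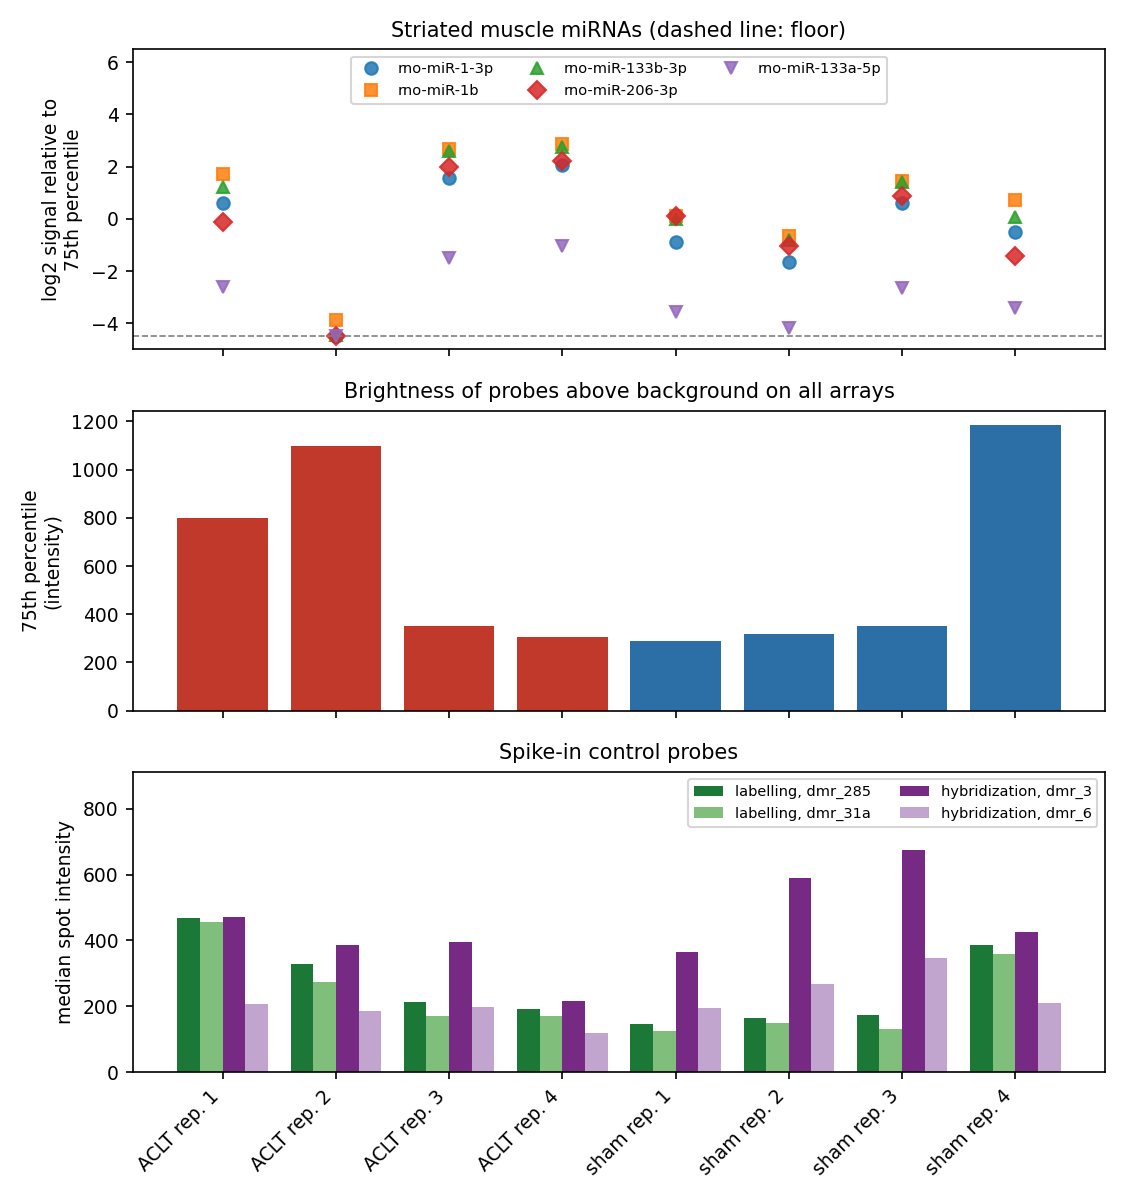
Per array, the log2 signal of 5 striated muscle miRNAs relative to the 75th percentile (top, dashed line at the floor of -4.48), the 75th percentile in intensity (middle, ACLT red and sham blue) and the median spot intensity of 4 spike-in control probes (bottom). ACLT replicate 2 lies at the floor for miR-1-3p, and ACLT replicates 1 and 2 and sham replicate 4 are the brightest arrays.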

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

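In this part, the fit with striated muscle as a covariate and the tests of why the arrays differ in striated muscle miRNA, why they differ in brightness and of the 8 miRNAs within slide row 1 were chosen after the result was seen.

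An array far from the other 3 of its group was found in 8 of 143 group values, where chance gives 7.15. The gap to the nearest array took up 0.904 of the group's range for miR-466b-5p on sham replicate 4 (at -4.48 against -2.86 to -2.69), 0.843 for miR-103-3p on ACLT replicate 1 (-2.08 against -1.85 to -1.81) and 0.855 for miR-23b-3p on sham replicate 3 (0.78 against 1.17 to 1.24). It took up 0.883 for miR-181d-5p on sham replicate 2 (-4.10 against -4.48 to -4.43). For miR-455-3p on sham replicate 1, miR-365-3p on sham replicate 4 and miR-539-5p on sham replicate 1 it was 1, because the other 3 arrays were at the floor. For the 75th percentile on sham replicate 4 it was 0.928 (1185 against 289 to 353).

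By limma 0 miRNAs passed between ACLT and sham (8 at an unadjusted p under 0.05), and since any split reaches at least 0, as 35 of the 35 splits of the 8 arrays did (highest other split 8), the splits say nothing about that count. Chance cannot be excluded for the other counts: as many as the real 8 at an unadjusted p under 0.05 came from 11 of 35 splits (highest other 31), and as many as the real 2 lists from 22 of 35 (highest other 6). The 5 splits that keep the 3 brightest arrays together gave 13 to 31, which points to a structure of the arrays other than the groups. The split by slide row gave 11 miRNAs and 4 lists. Within row 1 the real groups gave 25 miRNAs and within row 2 they gave 10. These fits held fewer arrays, and no splits were run within rows. Their counts therefore cannot be set against those of the 35 splits. Whether spread in striated muscle miRNA between arrays hides differences cannot be told apart from a lack of differences. With the mean muscle level as a covariate 0 of 108 miRNAs outside that list passed by limma, 7 had an unadjusted p under 0.05, of which 3 were higher after ACLT (8 and 0 without it), and miR-21-5p was at 0.75 and miR-34a-5p at 0.64 (limma adjusted p = 0.509 for both, over their alternatives 0.184 to 1 and 0.215 to 1).

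Striated muscle miRNAs spread over up to 146-fold between arrays. Brightness of the array is argued against as the whole source, since the mean muscle level differed 10.9-fold among the 5 dimmer arrays, which differed 1.22-fold in brightness, and at least 22.9-fold among the 3 brightest, which differed 1.49-fold (4.10-fold over all 8), a lower bound because 3 of the 5 members were at the floor on ACLT replicate 2. The operation stays open: 4 of 4 sham arrays lay within the range of the ACLT arrays, but 1 did without ACLT replicate 2. Striated muscle tissue in some of the samples is a candidate source: the 5 tested members, none of which is in another list, moved together, the lowest Pearson r of 10 pairs being 0.877 (exact permutation p = 0.00265, Spearman's rho 0.833 with exact permutation p = 0.0154; miR-133a-5p and miR-206-3p over 8 arrays), 0.787 without ACLT replicates 3 and 4, the 2 farthest from the median of miR-133a-5p, and 0.902 (exact permutation p = 0.00952, rho 0.75 with exact permutation p = 0.0663) without ACLT replicate 2, with a lowest r of 0.836 over the 10 pairs. On ACLT replicate 4, miR-1-3p reached 2.05 and miR-206-3p 2.24, while on ACLT replicate 2 both lay at the floor.

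ACLT replicates 1 and 2 and sham replicate 4 were brighter than the others. Hybridization or scanning is argued against, with 1 of the 3 among the brightest by the hybridization spike-in probes. Labelling of the RNA may account for at least part of the brightness, since 3 of 3 were the brightest by the labelling spike-in probes (chance 0.0179). Within the 3 the orders differed: sham replicate 4 led by the 75th percentile (1185) and ACLT replicate 1 by the labelling probe dmr_285 (470). The 8 miRNAs that passed within slide row 1, named here after their values were seen, were miR-1224, miR-181a-5p, miR-181b-5p, miR-32-3p, miR-466b-5p, miR-494-3p, miR-500-3p and miR-652-5p, by -0.75 to -2.69 relative to the array's 75th percentile and, unscaled, by -1.06 to 0.88, with 4 of the 8 positive. miR-32-3p, miR-466b-5p and miR-652-5p were at the floor on both ACLT arrays of row 1, and miR-181b-5p was so on ACLT replicate 2. The size of their scaled differences depends on the floor, which also narrows their spread. Brightness of the array may lie behind the 8 calls, as 8 of 8 were also lower on the bright sham replicate 4 than on the dim sham replicate 3, with no cut ligament in either. On sham replicate 4 miR-32-3p, miR-466b-5p, miR-652-5p and miR-181b-5p were at the floor, so for them only the direction of that step is known. The operation cannot be told apart from brightness in row 1, where both ACLT arrays were bright, and in row 2 the dim ACLT replicates 3 and 4 were both below sham replicate 3 for 6 of the 8.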

How the results depend on the processing

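In this part, the 75th percentile without striated muscle probes, the labelling spike-in scaling, normexp on median signals, the striated muscle covariate, the filter for probes well above background on all 8 arrays and the fit without the 3 brightest arrays were chosen after seeing the data. Normexp on mean signals was planned and not run. The count of miRNAs past the threshold was 0 (limma; 8 at an unadjusted p under 0.05) under all alternatives run but within slide row 1, where it was 8, all lower after ACLT; counts at an unadjusted p under 0.05 ran from 1 to 25. The 2 lists past camera became 0 with the 75th percentile over all probes, quantile normalization, no scaling, the Feature Extraction summary, the value table, within slide row 1, by camera with an estimated correlation and by fry. They became 1 with the mean over probes, the striated muscle covariate and the filter for well above background (the fibroblast list), and with array weights, within slide row 2 and without the 3 brightest arrays (striated muscle), and 0 to 2 when 1 array was left out; the cause was not tested. Of the alternatives that kept 2 lists, labelling spike-in scaling called striated muscle in place of the miR-23/27/24 clusters. The count was 3 with no filter and with normexp, which added striated muscle, with the 75th percentile without striated muscle probes, which added let-7, and with double the floor, which added the miR-99, miR-100 and miR-125 group. With the replicate block 0 miRNAs passed (limma; 4 at an unadjusted p under 0.05) and 1 list, the fibroblast list. The labels do not say whether equal numbers pair the arrays, and the values do not settle it. Across miRNAs, which are not independent replicates, same-numbered arrays correlated by -0.41 to 0.80 in their deviations from the group means. Of 4 ACLT arrays, 2 correlated best with their own number. The median of all tested miRNAs, -0.07, became 0.24, 0.19, 0.21, 0.062 and -0.26 with the 75th percentile over all probes, no scaling, the value table, the percentile without striated muscle probes and labelling spike-in scaling, and the turns in sign are relative to these. The difference in miRNAs detected per array, 5.5, ran from -4.08 to 21.9 when 1 array was left out. Signal over background limits the dim miRNAs, 33 of 113 being at the floor on some arrays and 2 on all. For lists the direction is that of the test, which camera sets against other miRNAs, so a median can keep its sign where the direction turned.

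Of 1573 values for 53 named miRNAs, 124 had the opposite sign, 4 newly passed and no other crossed the threshold; none of the 124 passed in either setting. Of 540 values for 17 lists, 48 had the opposite direction. Of the others, 10 newly passed and 36 no longer did. The miR-23/27/24 clusters with quantile normalization count among the 48 and lost their call as well. Log2 differences that turned with the 75th percentile over all probes were rno-miR-223-3p 0.061, rno-miR-196b-5p 0.081, rno-miR-143-3p 0.077, rno-miR-10a-5p 0.023, rno-miR-100-5p 0.15, rno-miR-181a-5p 0.059, rno-miR-142-3p 0.23, rno-miR-146a-5p 0.25, rno-miR-126a-3p 0.18. Others there were rno-miR-455-3p 0.36, rno-miR-103-3p 0.23, rno-miR-30b-5p 0.15, rno-miR-25-3p 0.20, rno-miR-92a-3p 0.11, rno-miR-15a-5p 0.12, rno-miR-16-5p 0.18, rno-miR-181d-5p 0.032, rno-miR-154-5p 0.25. Further ones there were rno-miR-365-3p 0.11. With no scaling they were rno-miR-223-3p 0.0077, rno-miR-196b-5p 0.028, rno-miR-143-3p 0.023, rno-miR-100-5p 0.093, rno-miR-181a-5p 0.0055, rno-miR-142-3p 0.17, rno-miR-146a-5p 0.20, rno-miR-126a-3p 0.12, rno-miR-455-3p 0.36. Others there were rno-miR-103-3p 0.17, rno-miR-30b-5p 0.10, rno-miR-25-3p 0.15, rno-miR-92a-3p 0.082, rno-miR-15a-5p 0.063, rno-miR-16-5p 0.13, rno-miR-181d-5p 0.012, rno-miR-154-5p 0.20, rno-miR-365-3p 0.025. In the authors' value table, unscaled, they were rno-miR-196b-5p 0.013, rno-miR-143-3p 0.017, rno-miR-10a-5p 0.11, rno-miR-100-5p 0.073, rno-miR-142-3p 0.27, rno-miR-146a-5p 0.18, rno-miR-126a-3p 0.11, rno-miR-455-3p 0.84, rno-miR-103-3p 0.14. Others there were rno-miR-30b-5p 0.10, rno-miR-25-3p 0.12, rno-miR-92a-3p 0.23, rno-miR-16-5p 0.11, rno-miR-154-5p 0.18, rno-miR-365-3p 0.44. Quantile normalization turned rno-miR-142-3p 0.16, rno-miR-455-3p 0.33, rno-let-7d-5p -0.029, rno-miR-25-3p 0.0088, rno-miR-92a-3p 0.091, rno-miR-27a-3p -0.096, rno-miR-154-5p 0.12, rno-miR-365-3p 0.026, rno-miR-23b-3p -0.14. Labelling spike-in scaling turned rno-miR-29b-3p -0.11, rno-miR-199a-5p -0.089, rno-miR-214-3p -0.083, rno-miR-206-3p -0.0019, rno-miR-455-3p 0.0041, rno-miR-107-3p -0.074, rno-miR-29a-3p -0.13, rno-miR-30e-5p -0.080, rno-let-7d-5p -0.043. Others there were rno-let-7g-5p -0.074, rno-miR-27a-3p -0.055, rno-miR-27b-3p -0.038, rno-miR-23b-3p -0.087. Leaving the striated muscle probes out of the percentile turned rno-miR-142-3p 0.037, rno-miR-146a-5p 0.059, rno-miR-103-3p 0.037, rno-miR-25-3p 0.013, rno-miR-154-5p 0.062. Fitted within slide row 1, these turned: rno-miR-142-3p 0.13, rno-miR-146a-5p 0.068, rno-miR-1-3p -0.66, rno-miR-206-3p -1.83, rno-miR-451-5p 0.36, rno-miR-30e-5p -0.23, rno-miR-15a-5p 0.13, rno-miR-27a-3p -0.042. Fitted within slide row 2, these turned: rno-miR-672-5p 0.064, rno-miR-181a-5p 0.11, rno-miR-29b-3p -0.15, rno-miR-103-3p 0.042, rno-miR-30b-5p 0.40, rno-let-7g-5p -0.033, rno-miR-494-3p 0.37, rno-miR-154-5p 0.12. Without the 3 brightest arrays these turned: rno-miR-140-3p -0.14, rno-miR-199a-5p -0.046, rno-miR-214-3p -0.14, rno-miR-30b-5p 0.0020. Normexp on the median signals turned rno-miR-29b-3p -0.044, rno-miR-107-3p -0.021, rno-miR-30e-5p -0.063. The Feature Extraction summary turned rno-miR-455-3p 0.53, rno-miR-92a-3p 0.052, rno-miR-365-3p 0.26, 0.5 times the floor rno-miR-455-3p 0.17, array weights rno-miR-214-3p -0.046 and the striated muscle covariate rno-miR-1-3p -0.022, rno-miR-206-3p -0.31. List medians where the direction of the test turned were, with quantile normalization, list leukocyte 0.030, list let-7 family -0.16, list miR-17-92 and paralogous clusters 0.091, list miR-23/27/24 clusters -0.14, list Dlk1-Dio3 imprinted cluster 0.058. Within slide row 1 they were list leukocyte -0.058, list erythroid -0.068, list adipose -0.20, list miR-30 family -0.64, list miR-17-92 and paralogous clusters -0.13, list miR-15/16 family 0.038. Within row 2 they were list inflammation-responsive 0.028, list let-7 family -0.033, list miR-181 family 0.11, list osteoarthritis-associated 0.11. Without scaling they were list leukocyte 0.14, list miR-17-92 and paralogous clusters 0.19, list miR-15/16 family 0.15. From the value table they were list leukocyte 0.18, list miR-17-92 and paralogous clusters 0.18, list miR-15/16 family 0.14. By directional fry they were list inflammation-responsive -0.046, list adipose -0.0054, list miR-30 family -0.084, list osteoarthritis-associated -0.073. The remaining turns were list inflammation-responsive -0.059 (without the 3 brightest arrays), list adipose -0.15 (0.5 times the floor), list adipose -0.11 (normexp on the median signals), list miR-30 family 0.11 (75th percentile without striated muscle probes), list miR-30 family -0.29 (labelling spike-in scaling), list miR-30 family -0.14 (striated muscle covariate), list miR-17-92 and paralogous clusters 0.24 (75th percentile over all probes), list miR-15/16 family -0.36 (labelling spike-in scaling), list Dlk1-Dio3 imprinted cluster 0 (double the floor), list osteoarthritis-associated -0.069 (without the 3 brightest arrays). Leaving out 1 array at a time turned a direction for these, given with their range: rno-miR-29b-3p -0.053 to 0.26, rno-miR-199a-5p -0.028 to 0.19, rno-miR-214-3p -0.060 to 0.21, rno-miR-1-3p -0.15 to 2.03, rno-miR-206-3p -0.50 to 1.74, rno-miR-455-3p -0.10 to 0.0079, rno-miR-107-3p -0.0019 to 0.20, rno-miR-29a-3p -0.031 to 0.11, rno-miR-30e-5p -0.042 to 0.25. The ranges of the others were rno-miR-23b-3p -0.012 to 0.15, list inflammation-responsive -0.12 to -0.0033, list erythroid -0.91 to -0.32, list adipose -0.049 to 0.022, list miR-30 family -0.24 to 0.14, list let-7 family -0.12 to 0.048, list miR-15/16 family -0.34 to -0.10, list Dlk1-Dio3 imprinted cluster -0.21 to -0.017.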

Other observations

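All tests in this part were chosen after the result was seen. Detection by the scanner software singled out few miRNAs, chosen here after their values were seen. miR-128-3p, a miRNA enriched in brain, and miR-300-3p, of the imprinted Dlk1-Dio3 region, were detected on 4 ACLT arrays and 1 sham array each, and miR-328a-5p on 0 ACLT arrays and 3 sham arrays (Fisher's exact test p = 0.143 each, adjusted p = 1 over 96 miRNAs). The signal of miR-300-3p was at the floor on all 8 arrays, so detection and level differ for it.

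The leading axis of variation between arrays held 64.0% of the variance, and the 5 miRNAs with the largest weights on it were all from the striated muscle list. The miRNAs were not brought to equal spread, so those that vary most between arrays weigh most, and the weights are no separate finding. On this axis ACLT replicate 2 lay at 9.69 and the other arrays at -5.56 to 2.60. The next axis held 23.5%. Neither separated ACLT from sham (exact two-sided permutation p = 0.886 and 0.171).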
